A study of Homo sapiens with 9 samples.

How the data were processed

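Poly(A) RNA was sequenced from 9 cultures of MCF10A cells, 3 each with vector only, deltaNp63alpha and deltaNp63beta, all after 500 ng/mL doxycycline for 24 h. The deposited signal values, per the submitters' processing notes, are normalized estimated counts per gene, made by the authors with kallisto 0.46.2 on GRCh38 and with DESeq2, whose version is not given. The notes do not say which step produced the deposited numbers. Each of the 9 files held 41857 Ensembl gene IDs, of which 36387 matched a gene symbol and 15915 were at 0 in all 9 libraries. A total of 239 symbols stood on more than 1 gene ID, and each gene was matched by ID. Gene positions came from GENCODE release 29. Of 194 named genes, 193 had a position, 97 overlapped another gene and 53 did so on the same strand.

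Whole read counts were not recovered from the files. Each library's low values lay on a step between 0.9232 and 1.1101, but only between 59.9% and 63.5% of the values up to 20 steps were whole multiples within 0.1 step. The test fixed before the data were examined, edgeR on rounded estimated counts, was not run, because the files held only normalized values. For that case a fallback had been fixed with it, and it was used. This was limma 3.58.1 in R 4.3.3 with trend and robust moderation on log2(value + 1), for genes with a value of at least 10 in at least 3 libraries. All 9 libraries entered 1 fit with a coefficient per group and no block, and Benjamini-Hochberg adjusted p under 0.05 was called. The pseudocount makes fold changes of genes with low values smaller than the ratio of their means. Of the 15108 genes tested, 13663 had a symbol, and the median SE of a log2 fold change was 0.109. A column sum of normalized values is not a depth, so the depth was taken from the sum and the step. No interval for counting error was computed, since the values are not counts. Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 were used for reading the files and drawing.

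Libraries of the same group correlated more closely than libraries of different groups, and the first and the next principal component held 40.8% and 15.2% of the variance. The replicate numbers did not pair the libraries. Residuals of libraries with the same number correlated at between -0.12 and 0.08 and those with different numbers at between -0.14 and 0.12, and 2 of 9 libraries correlated best with 1 of their own number. No batch or date is given in the labels.

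A total of 25 gene lists with 818 entries, 816 of them matched, were written before the data were examined. Each was tested with camera at a preset correlation of 0.01, adjusted over the lists of a comparison, and again with an estimated correlation. The text names the 10 largest rises and 10 largest falls per comparison among genes past the threshold with a mean of at least 2 CPM, a gene symbol and groups that do not overlap. It also names up to 4 members of each list by smallest adjusted p, TP63, TP73 and CDKN1A, and up to 6 genes that passed in opposite directions with the 2 isoforms. Where 5 or fewer members of a list moved against the rest, some of them were named as well, after their values were seen, but not in every list. Some of the genes that this rule picks, and 1 of the lists, are not reported here. The overlap of the comparisons with vector was set beside 20 simulations of unchanged groups against the same vector libraries.

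The fit was tested on simulated data, 15108 genes with added changes of 3 sizes in 67, 67 and 66 of them. For deltaNp63alpha against vector, 67.2%, 76.1% and 81.8% of genes changed 1.5-fold, 2-fold and 4-fold were recovered with 8 false calls, and for deltaNp63beta 64.2%, 77.6% and 89.4% with 13. The false calls were 5.1% and 7.8% of all calls. Far fewer genes were changed than the 14.5% and 41.3% called in the data, so these rates need not carry over. In both, 0 of 24 lists without an added change were called. These lists held random genes with independent noise. They do not test real lists whose members vary together, such as the mitochondrially encoded mRNAs, with an estimated correlation of 0.75.

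Alternatives fixed beforehand were median-of-ratios factors, 2 other filters on low values, only the 2 groups compared, a replicate block, a test against a 1.5-fold change, a pseudocount of 0.1, an estimated correlation, fry, and leaving out each library. Equal totals, quantile normalization, no mean-variance trend and library weights were added after seeing the data. So was leaving out genes without a position or with a symbol on more than 1 gene ID. That set was not chosen by sequence similarity, so it does not test reads shared between near-identical genes. DESeq2 and limma-voom were planned but need counts and were not run.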

Results

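RNA was measured in 9 libraries of MCF10A, a non-tumorigenic human mammary epithelial cell line grown in medium with serum, epidermal growth factor, insulin, hydrocortisone and cholera toxin. The cells carried an empty vector, human deltaNp63alpha or human deltaNp63beta, with 3 biological replicates of each. The isoforms are N-terminally truncated forms of the transcription factor p63 that share their DNA-binding domain and differ in their C-terminal part. All 9 cultures, vector included, received 500 ng/mL doxycycline for 24 h. The deposited values were normalized estimated counts for 41857 genes per library, and each library summed to between 22.5 and 23.2 M (mega). The step between the lowest values of a library put its depth before normalization at about 20.3 to 24.4 M estimated fragments. Of these genes, 15108 passed the filter on low values and were tested. Group values below are mean ± SD of n = 3 libraries, and changes are log2 fold changes ± SE on the log2(value + 1) scale, with adjusted p from limma.

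TP63 (ENSG00000073282, GRCh38 chromosome 3, 189631416 to 189897279, plus strand, protein coding) was the transgene, and its RNA separates the vector libraries from the transgene libraries but not deltaNp63alpha from deltaNp63beta. Its level was 302.3 ± 38.1 with vector, 6123 ± 1470 with deltaNp63alpha and 5257 ± 1312 with deltaNp63beta. The vector libraries held 316, 332 and 259, the deltaNp63alpha libraries 4426, 6983 and 6961, and the deltaNp63beta libraries 6719, 4183 and 4870. The change against vector was 4.31 ± 0.21 for deltaNp63alpha (adjusted p = 1.91e-06) and 4.09 ± 0.21 for deltaNp63beta (adjusted p = 6.2e-07). Between the isoform groups TP63 differed by -0.22 ± 0.21 (adjusted p = 0.48), which did not exceed the spread between replicates. The gene-level value does not separate transgene from endogenous transcripts, and protein was not measured here.

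**Figure D1:**
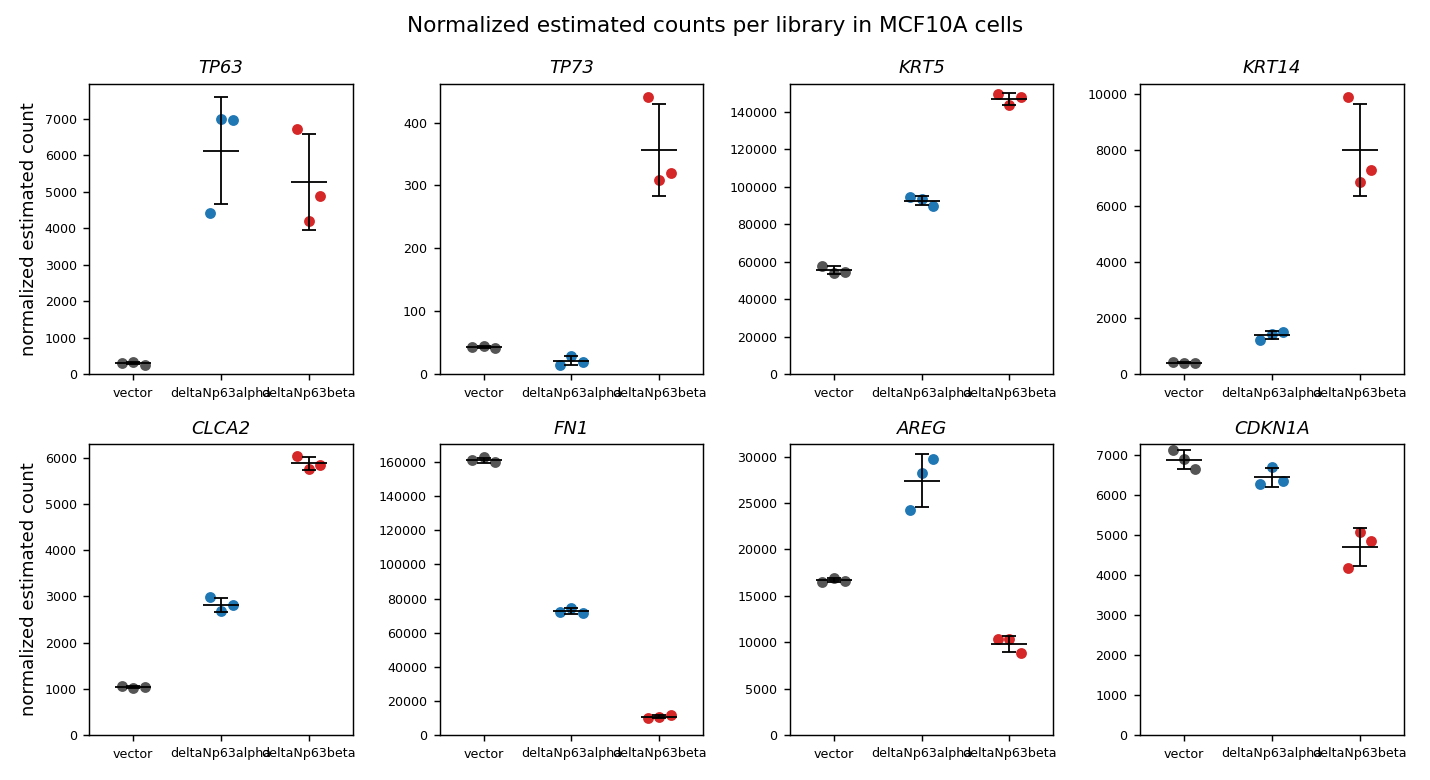
Normalized estimated counts (linear y axes starting at 0) of 8 genes in each of the 9 libraries, by group; points are libraries, the horizontal mark is the group mean and the error bar its SD (n = 3). TP63 was about equally high in both isoform groups, KRT14 averaged 411 with vector, 1383 with deltaNp63alpha and 8009 with deltaNp63beta, and FN1 averaged 161234, 72775 and 10669 in the same order.

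The first comparison asked which genes deltaNp63alpha changed against vector. Desmosome genes, basal markers and direct p63 targets rose, and mesenchymal and EMT genes fell. CLCA2, a p63 target that encodes an epithelial surface protein, rose from 1037 ± 29.5 to 2824 ± 153 (1.44 ± 0.05, adjusted p = 3.2e-08). COL17A1, a hemidesmosomal collagen, rose from 7688 ± 287 to 17159 ± 889 (1.16 ± 0.05, adjusted p = 8.1e-08). FN1, which encodes fibronectin, fell from 161234 ± 1453 to 72775 ± 1629 (-1.15 ± 0.04, adjusted p = 4.1e-08). In all, 1229 genes were higher and 963 lower, 14.5% of those tested, and 211 and 130 of them changed at least 2-fold. The number lower was between 640 and 771 on leaving out any 1 deltaNp63alpha or vector library, and between 897 and 1022 without any 1 deltaNp63beta library. With a test against a 1.5-fold change, 134 genes were higher and 47 lower.

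Among genes known as direct p63 targets, 26 rose and 2 fell of 38 tested (27 and 2 adjusted over the list alone; camera adjusted p = 1.09e-20, and adjusted p = 0.0067 with an estimated correlation). PERP rose by 0.73 ± 0.03 and KRT5, the basal keratin, from 55464 ± 2111 to 92598 ± 2467. The targets that fell were SAMD9L (-0.84 ± 0.19, not called without vector replicate 1, adjusted p = 0.0545) and IGFBP3 (-1.13). Of the basal keratins and basal epithelial markers, 14 rose and 2 fell of 22 tested (15 and 2 adjusted over the list alone; camera adjusted p = 1.64e-12, and adjusted p = 0.00246 with an estimated correlation). KRT17 rose by 1.29 ± 0.05, KRT6A by 0.94 ± 0.04 and S100A2 by 1.60 ± 0.09, while ACTA2 fell, as did KRT16, not called without vector replicate 1 (adjusted p = 0.0509). KRT6A, KRT14, KRT16 and KRT17 have near-identical relatives, so fragments could be divided between them. Desmosome genes, which encode cell to cell junction proteins, rose in 11 of 12 cases with none lower (12 and 0 adjusted over the list alone; camera adjusted p = 7.17e-15, and adjusted p = 0.00246 with an estimated correlation). DSG3 rose by 1.16 ± 0.06, DSC3 by 1.04 ± 0.07 and DSP by 0.46 ± 0.04.

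Mesenchymal and EMT genes fell in 19 of 29 cases and rose in 1 (20 and 1 adjusted over the list alone; camera adjusted p = 6.12e-15, and adjusted p = 0.00267 with an estimated correlation). Besides FN1, the calcium-binding protein gene S100A4 changed by -1.16 ± 0.06, N-cadherin (CDH2) by -0.73 ± 0.05, and TGFBI by -0.84 ± 0.04. The gene that rose was TNC, not called without deltaNp63alpha replicate 2 or 3, deltaNp63beta replicate 2 or any 1 vector library (adjusted p between 0.0553 and 0.148). POSTN, which encodes the matrix protein periostin, went from 748 ± 41.8 to 106.3 (-2.83 ± 0.28), the largest fall among the genes named. Hemidesmosome and basement membrane adhesion genes rose in 11 and fell in 3 of 27 cases (12 and 4 adjusted over the list alone; camera adjusted p = 0.00233, but adjusted p = 0.305 with an estimated correlation). LAMA3 (0.88 ± 0.04), DST (0.83 ± 0.04) and ITGA6 (0.74 ± 0.04) rose, and the type IV collagens COL4A1 and COL4A2 and the integrin gene ITGAV fell.

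Immediate early genes, which respond fast to growth factors, rose in 17 and fell in 4 of 39 cases (18 and 7 adjusted over the list alone; camera adjusted p = 0.00026, but adjusted p = 0.0968 with an estimated correlation). HBEGF rose by 1.27 ± 0.10, DUSP5 by 0.87 ± 0.08, PHLDA1 by 0.78 ± 0.05 and FOSL1 by 0.53 ± 0.05. NRF2 antioxidant genes fell in 9 and rose in 3 of 28 cases (11 and 3 adjusted over the list alone; camera adjusted p = 0.000577, but adjusted p = 0.0808 with an estimated correlation). AKR1C2 changed by -1.17 ± 0.08, the ferritin genes FTH1 by -0.85 ± 0.04 and FTL by -0.60 ± 0.04, and the transporter gene ABCC3 by -0.96 ± 0.10. The AKR1C genes share much of their sequence, and ferritin genes have many processed pseudogenes. Cornification and squamous differentiation genes rose in 8 and fell in 2 of 30 cases (10 and 2 adjusted over the list alone; camera adjusted p = 0.0324, but adjusted p = 0.189 with an estimated correlation and adjusted p = 0.073 without vector replicate 2). TGM1 rose by 1.28 ± 0.12 and S100A9 by 1.61 ± 0.15, and KRT80 fell. Luminal epithelial markers rose in 7 and fell in 2 of 17 cases (8 and 3 adjusted over the list alone; camera adjusted p = 0.0324, but adjusted p = 0.13 with an estimated correlation, 0.0528 without vector replicate 2 and 0.0554 after quantile normalization). EPCAM rose by 0.84 ± 0.10 and KRT8 changed by -0.30 ± 0.05.

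CDKN1A, the cell cycle inhibitor p21, was at 6887 ± 232 with vector and 6445 ± 234 with deltaNp63alpha (-0.10 ± 0.07, adjusted p = 0.39). The Notch pathway had 6 genes higher and 3 lower of 22 (7 and 4 adjusted over the list alone; camera adjusted p = 0.143), with JAG1 up by 0.81 ± 0.06. TGF-beta response genes had 5 higher and 10 lower of 29 (6 and 10 adjusted over the list alone; camera adjusted p = 0.0769, and 0.0416 without deltaNp63alpha replicate 2). YAP and TEAD target genes had 6 higher and 5 lower of 24 (7 and 7 adjusted over the list alone; camera adjusted p = 0.867; 6 and 6 with equal totals or quantile normalization), with a median of 0.03 and a mean of -0.07. Cell cycle and E2F genes had 6 higher and 1 lower of 50 (6 and 1 adjusted over the list alone; camera adjusted p = 0.15). Lists of cell types that the line should lack were tested as well. The fibroblast markers DCN and FBLN1 fell and none rose of 6 tested (2 and 0 adjusted over the list alone; camera adjusted p = 0.025, but adjusted p = 0.124 with an estimated correlation), the leukocyte markers CD68 and ITGB2 fell of 5 tested (2 adjusted over the list alone; camera adjusted p = 0.15), and the endothelial marker PECAM1 was lower of 4 tested (1 adjusted over the list alone; camera adjusted p = 0.096). PECAM1 was no longer called without deltaNp63alpha replicate 1 or 3 or vector replicate 2 (adjusted p = 0.0654, 0.0667 and 0.0767).

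Besides TP63 itself, the largest rises with deltaNp63alpha were in genes with little RNA in vector cells. TREM2, a receptor best known from myeloid cells (GRCh38 chromosome 6, 41158506 to 41163186, minus strand), was listed at 0, 0 and 1.17 in the vector libraries and averaged 120.4 ± 11.2 with deltaNp63alpha. NLRP3, the inflammasome sensor, rose from 10.4 ± 8.78 to 151.7 ± 32.5, ARHGAP25 from 9.46 to 136.9, MRGPRX3 from 5.20 to 98.4, and SPINK5, a skin protease inhibitor, from 16.8 ± 3.66 to 131.5 ± 18.9. NIPAL4, BDKRB2 and LTB4R2 rose by between 2.36 and 3.09. FKBPL was uneven, at 174, 5.69 and 6.13 in the deltaNp63alpha libraries, and its call was lost without deltaNp63beta replicate 2 (adjusted p = 0.0513) or vector replicate 1, 2 or 3 (adjusted p = 0.127, 0.081 and 0.082). The other large falls were in PAPPA, SCNN1B, DGKI, FPR1, VGF, RERG, ALOX5AP and ANGPT1, from -2.28 ± 0.21 for PAPPA to -1.85 ± 0.29 for ANGPT1. DGKI was not called without deltaNp63alpha replicate 1 or 3 or any 1 vector library (adjusted p between 0.0622 and 0.0868).

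The comparison of deltaNp63beta with vector asked the same question of the other isoform. Cornification and desmosome genes rose, and mesenchymal, EMT and TGF-beta response genes fell. DSG3, a desmosomal cadherin, rose from 969 ± 81.9 to 7685 ± 143 (2.99 ± 0.06, adjusted p = 6.17e-11). KRT14 rose from 411 ± 32.5 to 8009 ± 1638 (4.26 ± 0.13, adjusted p = 8.15e-10). FN1 (GRCh38 chromosome 2, 215360440 to 215436172, minus strand) fell to 10669 ± 694 (-3.92 ± 0.04, adjusted p = 4.0e-13). In all, 3293 genes were higher and 2953 lower, 41.3% of those tested, and 609 and 601 of them changed at least 2-fold. With a test against a 1.5-fold change, 516 were higher and 387 lower.

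Of the direct p63 targets, 30 rose and 2, IGFBP3 and FERMT1, fell of 38 (30 and 2 adjusted over the list alone; camera adjusted p = 1.7e-14, and adjusted p = 0.0177 with an estimated correlation). PERP rose by 1.77 ± 0.03 and KRT5 by 1.41 ± 0.03, to 146977 ± 3242. Basal markers rose in 15 and fell in 4 of 22 cases (15 and 4 adjusted over the list alone; camera adjusted p = 1.74e-06, and adjusted p = 0.0122 with an estimated correlation). KRT17 rose by 3.44 ± 0.05 and P-cadherin (CDH3) by 2.11 ± 0.08, and the genes that fell were MYLK, CAV1, SNAI2 and, near the threshold, ACTA2, which was not called on leaving out any 1 library except deltaNp63beta replicate 2 (adjusted p between 0.0609 and 0.169). Desmosome genes rose in 11 of 12 cases with none lower (12 and 0 adjusted over the list alone; camera adjusted p = 6.2e-11, and adjusted p = 0.00486 with an estimated correlation), with PPL up by 2.02 ± 0.07. Cornification and squamous differentiation genes rose in 22 and fell in 3 of 30 cases, with a median change of 2.56 (22 and 4 adjusted over the list alone; camera adjusted p = 1.51e-06, and adjusted p = 0.0195 with an estimated correlation). TGM1, a crosslinking enzyme of the cornified envelope, rose by 4.09 ± 0.12, the transcription factor gene GRHL3 by 4.64 ± 0.22, the elastase inhibitor gene PI3 by 3.86 ± 0.11 and S100A9 by 3.54 ± 0.15. Luminal epithelial markers rose in 10 and fell in 3 of 17 cases (12 and 3 adjusted over the list alone; camera adjusted p = 6.28e-05, and adjusted p = 0.0195 with an estimated correlation). EPCAM rose by 3.04 ± 0.10, CLDN7 by 3.16 ± 0.11 and SLPI by 2.85 ± 0.09, while the keratin genes KRT7 and KRT19 and the prolactin receptor gene PRLR fell. After quantile normalization KRT7 and PRLR were not called (adjusted p = 0.153 and 0.0651). KRT7 was not called either without vector replicate 1 or 2 (adjusted p = 0.0672 and 0.0527), nor PRLR without deltaNp63beta replicate 1 or 2 or vector replicate 2 or 3 (adjusted p between 0.0651 and 0.092).

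Mesenchymal and EMT genes fell in 26 of 29 cases with none higher (26 and 1 adjusted over the list alone; camera adjusted p = 7.87e-17, and adjusted p = 0.00486 with an estimated correlation). TGFBI changed by -2.16 ± 0.04 and S100A4 by -2.26 ± 0.06. TGF-beta response genes, which share members such as FN1, TGFBI and THBS1 with that list, fell in 19 and rose in 4 of 29 cases (19 and 5 adjusted over the list alone; camera adjusted p = 1.65e-06, and adjusted p = 0.0338 with an estimated correlation). YAP and TEAD target genes fell in 14 and rose in 4 of 24 cases (14 and 4 adjusted over the list alone; camera adjusted p = 0.000618, but adjusted p = 0.132 with an estimated correlation). CCN2 changed by -2.33 ± 0.07, CCN1 by -1.44 ± 0.04 and AXL by -1.17 ± 0.04. Immediate early genes fell in 20 and rose in 9 of 39 cases (21 and 10 adjusted over the list alone; camera adjusted p = 0.00195, but adjusted p = 0.105 with an estimated correlation), and FOSL1 changed by -1.11 ± 0.05 while BTG2 rose by 1.76 ± 0.09. NRF2 antioxidant genes rose in 19 and fell in 4 of 28 cases (19 and 4 adjusted over the list alone; camera adjusted p = 6.91e-05, and adjusted p = 0.0345 with an estimated correlation). AKR1B10 rose from 11.1 ± 2.45 to 322 ± 74.9, AKR1C1 by 1.14 ± 0.07, GCLC by 0.84 ± 0.05 and TKT by 0.69 ± 0.04, and FTH1, TXNRD1 and ABCC3 were among those that fell.

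The Notch pathway had 13 genes higher and 5 lower of 22 (13 and 5 adjusted over the list alone; camera adjusted p = 0.00637, but adjusted p = 0.0875 with an estimated correlation). HES2 rose by 3.20 ± 0.13, NRARP by 2.22 ± 0.14 and NOTCH1 by 0.97 ± 0.07. Hemidesmosome and basement membrane genes went both ways, 15 higher and 8 lower of 27 (15 and 8 adjusted over the list alone; camera adjusted p = 0.0861, and 0.045 without deltaNp63beta replicate 1). DST rose by 1.33 ± 0.04 and LAMB1 by 0.95 ± 0.04, and LAMB3 changed by -0.51 ± 0.06. CDKN1A changed by -0.56 ± 0.07. Cell cycle and E2F genes had 17 higher and 8 lower of 50 (17 and 9 adjusted over the list alone; camera adjusted p = 0.756), and the test pointed up with a median of -0.01 and a mean of -0.02. The counts were 15 and 15 with equal totals and 16 and 13 after quantile normalization, so they did not lean to 1 side under every scaling. CCNA2 rose by 0.40 ± 0.04 and E2F1 changed by -0.98 ± 0.10. Of 6 fibroblast markers, COL1A1, FBLN1 and MFAP5 rose and DCN fell (3 and 1 adjusted over the list alone; camera adjusted p = 0.547). The fibroblast median was 0.47 and the mean -0.04, and the leukocyte median -0.86 and the mean 0.02. COL1A1 was not called without vector replicate 2 or 3 or any 1 deltaNp63beta library (adjusted p between 0.0529 and 0.0886). Of 5 leukocyte markers, CD14 and LAPTM5 rose and CD68, CSF1R and ITGB2 fell (2 and 3 adjusted over the list alone; camera adjusted p = 0.385), and of 4 endothelial markers PECAM1, KDR and TEK fell (0 and 3 adjusted over the list alone; camera adjusted p = 0.158).

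Among the largest rises with deltaNp63beta, TMEM265 was listed at 0 in every vector and deltaNp63alpha library and at 183, 180 and 83.3 in the deltaNp63beta libraries. TMEM265 overlaps other genes on the same strand, SRCAP among them, so its value is uncertain. IGFL1 rose by 5.73 ± 0.34, SERPINB3 by 5.67 ± 0.57, SERPINB2 by 4.52 ± 0.28, TREM2 by 4.78 ± 0.40, NIPAL4 by 4.59 ± 0.22, TRAF3IP3 by 4.40 ± 0.44 and FKBPL by 6.89 ± 1.02. The largest falls were in DGKI (-5.55 ± 0.53), SCG5 (-5.15 ± 0.68), CHRNA9 (-4.74 ± 0.19), POSTN (-4.43 ± 0.28), COL6A3 (-4.38 ± 0.13) and ALOX5AP (-4.01 ± 0.34), followed by FN1, CGB8, GCNA and MPO.

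**Figure D2:**
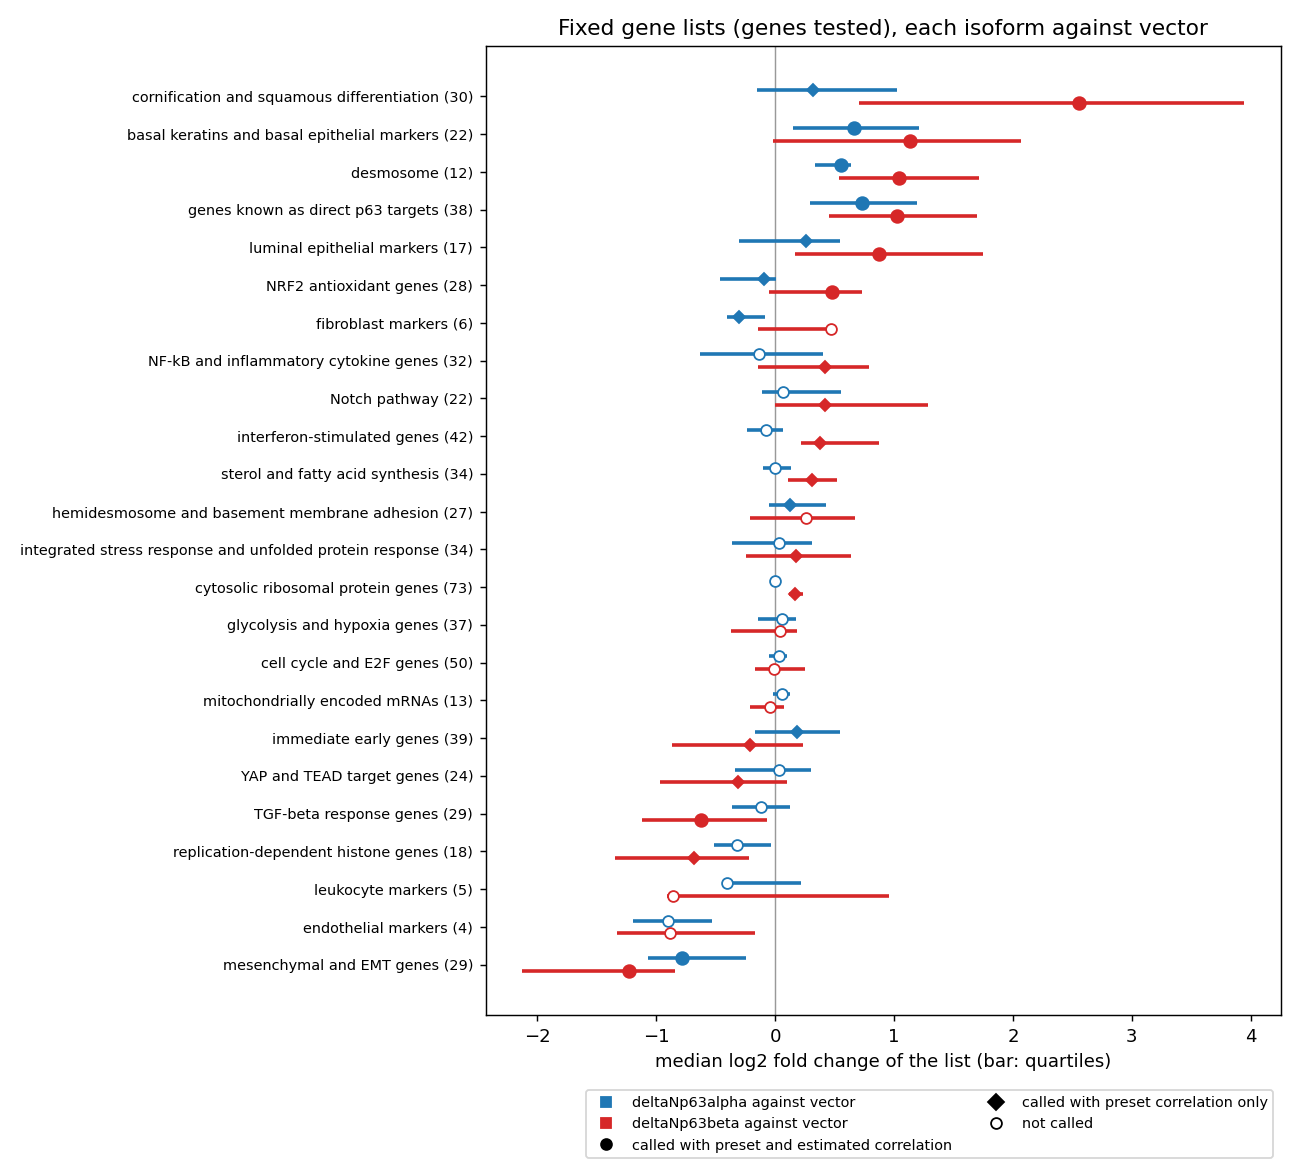
Median log2 fold change (x axis) of 24 of the 25 fixed gene lists against vector with deltaNp63alpha (blue) and deltaNp63beta (red); bars span the quartiles over the tested members, whose number follows the list's name, and the marker shows whether camera called the list. Cornification genes had a median of 0.32 with deltaNp63alpha and 2.56 with deltaNp63beta, and mesenchymal genes -0.78 and -1.23.

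The direct comparison of the 2 isoform groups asked where deltaNp63beta and deltaNp63alpha differ. Cornification, desmosome and antioxidant genes were higher with deltaNp63beta, and mesenchymal, EMT and immediate early genes were lower. CLDN1, a tight junction gene, averaged 2752 ± 55.2 with deltaNp63beta and 190 ± 26.1 with deltaNp63alpha (3.86 ± 0.10, adjusted p = 1.47e-09). FN1 differed by -2.77 ± 0.04 (adjusted p = 1.8e-11). In all, 2625 genes were higher and 2340 lower with deltaNp63beta, 32.9% of those tested, and 407 and 418 of them differed at least 2-fold. With a test against a 1.5-fold change, 231 were higher and 187 lower.

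NRF2 antioxidant genes were higher with deltaNp63beta in 21 of 28 cases and lower in none (22 and 0 adjusted over the list alone; camera adjusted p = 8.67e-13, and adjusted p = 0.0107 with an estimated correlation). AKR1B10 differed by 4.85 ± 0.29, AKR1C2 by 1.81 ± 0.08 and PIR by 1.12 ± 0.07. Immediate early genes were lower in 23 and higher in 5 of 39 cases (23 and 7 adjusted over the list alone; camera adjusted p = 2.45e-07, and adjusted p = 0.0269 with an estimated correlation), with FOSL1 at -1.63 ± 0.05, KLF6 at -1.07 ± 0.04 and CCN1 at -1.53 ± 0.04. CCN1 was also named above among the YAP and TEAD target genes, so the falls of these lists are not independent of each other. Mesenchymal and EMT genes were lower in 17 cases and 1, COL12A1, was higher of 29 (20 and 1 adjusted over the list alone; camera adjusted p = 1.71e-10, and adjusted p = 0.0107 with an estimated correlation). TGF-beta response genes were lower in 17 and higher in 3 of 29 cases (20 and 4 adjusted over the list alone; camera adjusted p = 6.38e-07, and adjusted p = 0.0269 with an estimated correlation), and THBS1 differed by -1.19 ± 0.05. YAP and TEAD target genes were lower in 13 and higher in 2 of 24 cases (14 and 2 adjusted over the list alone; camera adjusted p = 6.38e-07, but adjusted p = 0.0531 with an estimated correlation), with F3, the tissue factor gene, at -1.27 ± 0.06.

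Desmosome genes were higher in 8 of 12 cases and lower in none (8 and 0 adjusted over the list alone; camera adjusted p = 1.19e-06, and adjusted p = 0.0163 with an estimated correlation). Cornification genes were higher in 17 and lower in 3 of 30 cases (19 and 4 adjusted over the list alone; camera adjusted p = 3.57e-06, and adjusted p = 0.0269 with an estimated correlation), with TGM1 at 2.81 ± 0.12 and S100A9 at 1.92 ± 0.15. Luminal markers were higher in 10 cases and 1, KRT7, was lower of 17, but not after quantile normalization (adjusted p = 0.513; 10 and 2 adjusted over the list alone; camera adjusted p = 4.45e-05, and adjusted p = 0.0269 with an estimated correlation). Direct p63 targets were higher in 19 and lower in 8 of 38 cases (21 and 9 adjusted over the list alone; camera adjusted p = 0.000154, but adjusted p = 0.104 with an estimated correlation). CLCA2 was higher by 1.06 ± 0.05 and PERP by 1.05 ± 0.03. Basal markers were higher in 11 and lower in 5 of 22 cases (12 and 6 adjusted over the list alone; camera adjusted p = 0.0138, but adjusted p = 0.0566 with an estimated correlation). KRT16 differed by 3.79 ± 0.14, KRT14 by 2.52 ± 0.13 and KRT17 by 2.16 ± 0.05. Hemidesmosome and basement membrane genes were higher in 12 and lower in 11 of 27 cases, 10 and 13 with equal totals and 11 and 11 after quantile normalization (12 and 13 adjusted over the list alone; camera adjusted p = 0.458). Of the laminin chains, LAMB3 was lower by -0.99 ± 0.06 and LAMA3 by -0.58 ± 0.04, and LAMB1 was higher by 1.07 ± 0.04.

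The Notch pathway had 9 genes higher and 5 lower of 22 (9 and 5 adjusted over the list alone; camera adjusted p = 0.098), with NRARP at 2.62 ± 0.14 and HES1 at 0.98 ± 0.08. CDKN1A differed by -0.46 ± 0.07. Cell cycle genes had 10 higher and 13 lower of 50 (12 and 14 adjusted over the list alone; camera adjusted p = 0.623). Fibroblast markers had 3 higher and 1 lower of 6 (3 and 1 adjusted over the list alone; camera adjusted p = 0.196), leukocyte markers 2 higher and 3 lower of 5 (2 and 3 adjusted over the list alone; camera adjusted p = 0.522) and endothelial markers 1 higher and 2 lower of 4, 1 and 1 after quantile normalization (1 and 2 adjusted over the list alone; camera adjusted p = 0.623). The median and mean were -0.46 and 0.29 for the leukocyte markers and -0.25 and 0.21 for the endothelial markers. Among the largest differences, besides TMEM265, were IGFL1 (4.97 ± 0.34), GRHL3 (4.79 ± 0.22), TRAF3IP3 (4.53 ± 0.44), TP73 (4.06 ± 0.25), RHOV (3.98 ± 0.11) and S100P (3.74 ± 0.19) upward. Downward they were MPO (-4.00 ± 0.42), SCG5 (-3.62 ± 0.68), CHRNA9 (-3.61 ± 0.19), DGKI (-3.47 ± 0.53), GCNA (-3.40 ± 0.37), COL6A3 (-2.85 ± 0.13), SEMA3B (-2.81 ± 0.07) and SHISAL1 (-2.80 ± 0.28). DSEL was uneven within groups, at 233, 86.1 and 291 with deltaNp63alpha and at 57.0, 0 and 0 with deltaNp63beta. Its call was lost without any 1 deltaNp63alpha library, deltaNp63beta replicate 2 or 3, or vector replicate 1 or 3 (adjusted p between 0.0519 and 0.141).

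**Figure D3:**
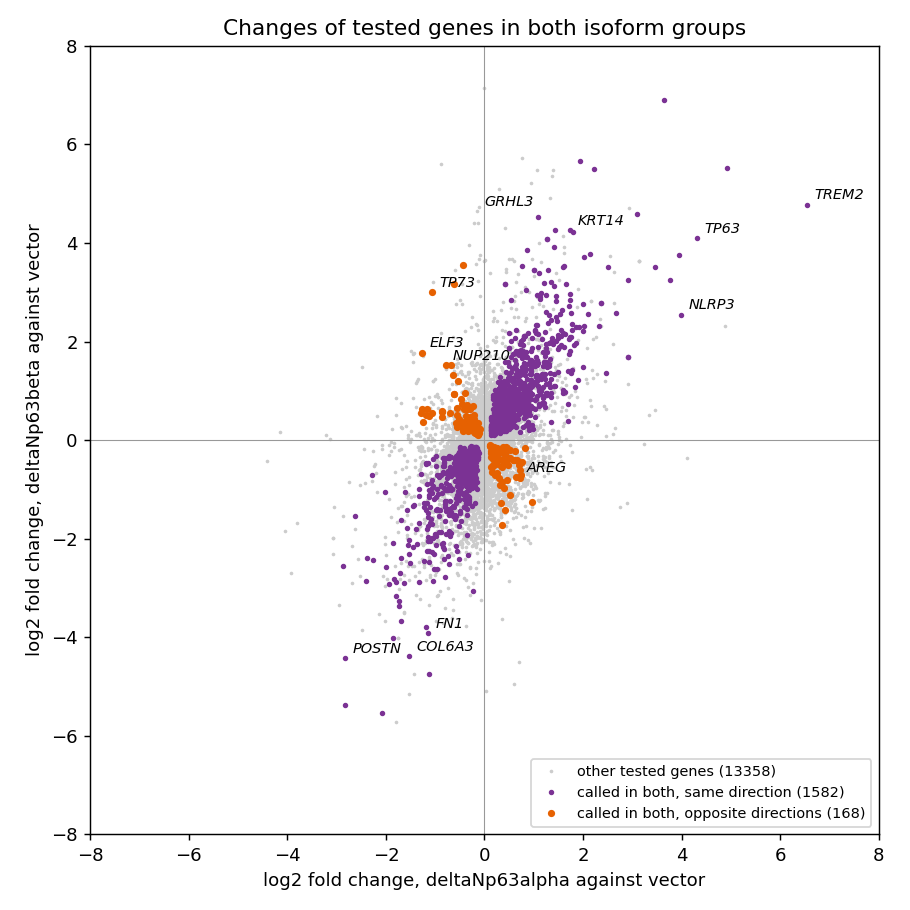
Log2 fold change against vector of the 15108 tested genes with deltaNp63alpha (x axis) and deltaNp63beta (y axis); each point is a gene, and color marks the 1582 genes called in the same direction and the 168 called in opposite directions. Both axes use the same 3 vector libraries as control.

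Across the 2 comparisons with vector, 915 genes were higher with both isoforms and 667 lower with both. Independent lists of these sizes would share 268 and 188, and 20 simulations of unchanged groups against the same vector libraries gave a mean of 0 and 0.05. That is chance with no effect, and does not measure what shared controls add among changed genes. Of the genes higher with deltaNp63alpha, 74.5% were also higher with deltaNp63beta, and of those lower, 69.3% were also lower. Among the shared rises, 394 were higher with deltaNp63beta than with deltaNp63alpha and 53 lower, and among the shared falls, 292 were lower and 29 higher. A set of 168 genes went in opposite directions, 78 of them higher with deltaNp63alpha and lower with deltaNp63beta and 90 the reverse, where independent lists would give 450. Of the 4496 genes called with deltaNp63beta alone, 2987 also differed between the isoform groups, as did 310 of the 442 called with deltaNp63alpha alone. Across genes, which are not independent replicates, the log2 fold changes correlated with Pearson r = 0.52, and the simulations gave a mean of 0.50 (0.47 to 0.53). The covariance was 0.187 against a simulated 0.0457, a difference of 0.141. With 3 vector libraries the controls could not be split into sets of 2, so part of the overlap may come from the shared controls.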

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

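All tests of explanations in this part were chosen after the results were seen. The comparison between the isoform groups was planned.

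A total of 168 genes, and 2 gene lists each taken as a set, changed in opposite directions with deltaNp63alpha and with deltaNp63beta against vector. Single members of the 2 lists did not all turn. FOSL1 did, but FTH1 and ABCC3 fell with both isoforms, and HBEGF lay above vector in every library of both. Of the list calls, those of the NRF2 antioxidant genes with deltaNp63alpha and of the immediate early genes with both isoforms were lost (adjusted p = 0.0808, 0.0968 and 0.105 with an estimated correlation), and that of the NRF2 list with deltaNp63beta was kept (0.0345). The 6 genes with the largest smaller change of the 2 are given here, by a rule fixed before the data were examined. For the genes, the difference between the isoforms follows from these 2 calls in a shared fit and is no further test of them. The lists were picked by their camera calls in the same fit, including that between the isoforms, so their difference is no independent test either. TP73, a relative of TP63, averaged 43.2 ± 1.85 with vector, 20.9 ± 7.20 with deltaNp63alpha and 356 ± 73.5 with deltaNp63beta, and differed by 4.06 ± 0.25 between the isoforms. ELF3, an epithelial transcription factor, differed by 3.04 ± 0.33 and the nuclear pore gene NUP210 by 2.30 ± 0.14. AREG, which encodes the growth factor amphiregulin, averaged 16679 ± 216 with vector, 27431 ± 2832 with deltaNp63alpha and 9847 ± 867 with deltaNp63beta, a difference of -1.48 ± 0.08. WNT9A differed by -1.46 ± 0.18 and DIPK2B by -2.22 ± 0.29. NRF2 antioxidant genes differed with camera adjusted p = 8.67e-13 and immediate early genes with 2.45e-07 (adjusted p = 0.0107 and 0.0269 with an estimated correlation). Among the 6 genes, the change of ELF3 with deltaNp63alpha was not called without deltaNp63alpha replicate 1 or 2 or vector replicate 1 or 2 (adjusted p = 0.0712 to 0.0914), with only the 2 groups compared (0.0904) or with a replicate block (0.0581). That of WNT9A with deltaNp63alpha was not called without deltaNp63alpha replicate 1 or 3 or vector replicate 1 (adjusted p = 0.0546 to 0.0625). That of DIPK2B with deltaNp63alpha was not called without any 1 deltaNp63alpha or vector library or deltaNp63beta replicate 3 (adjusted p = 0.0543 to 0.151), nor under 5 other settings (0.0526 to 0.0822). That of TP73 with deltaNp63alpha was not called with only the 2 groups compared (adjusted p = 0.0524).

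The number of genes called was 6246 with deltaNp63beta and 2192 with deltaNp63alpha. A larger amount of 1 shared response that keeps its direction at every dose would move genes the same way. Of the genes called in both, 1582 did so and 168, or 9.6%, went in opposite directions, where independent lists would give 450. The cutoff for this share was set after the data were seen, and the 168 were not counted again under other settings. They argue against such a response as the whole cause, but not against a response whose direction depends on dose. Depth does not account for the difference either, since its mean was 23.2 M in both groups (23.1823 with deltaNp63beta and 23.1779 with deltaNp63alpha). The median SD within groups was 0.126 with deltaNp63beta and 0.115 with deltaNp63alpha, which tests nothing here, since each gene had 1 spread pooled over the groups. Protein levels of the isoforms were not measured here, and differences between the cell populations carrying each construct cannot be told apart from the isoform.

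For TP73, fragments of the TP63 transgene assigned to TP73 would raise it in both isoform groups, and its change with deltaNp63alpha was -1.06 ± 0.25. Another scaling of the libraries kept 4 of 4 results of TP73 against vector. Equal totals put the median change over all genes at -0.02 with deltaNp63alpha and -0.04 with deltaNp63beta. That is too little to turn the direction of TP73, so its results there test little. A difference in the action of the isoforms on TP73 may remain as a hypothesis, found and tested on the same data. TP73 overlaps genes on the opposite strand, which was not tested.

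For the NRF2 and immediate early lists, another scaling of the libraries kept 12 of 12 results. Equal totals moves the genes of a library nearly alike, and camera compares a list with other genes, so only the results after quantile normalization test this. Without 8 members with near-identical relatives, chosen by name, the NRF2 list of 20 was still higher with deltaNp63beta than with deltaNp63alpha (camera adjusted p = 6.03e-08). The median difference was 0.46 over these 20, 0.55 over all 28 and 1.25 over the 8 left out. This argues against reads shared by those 8 as the whole source of that difference. The 20 kept were not checked for sequence similarity. For the fall with deltaNp63alpha against vector, the same test gave adjusted p = 0.15 and the call ended, as the median went from -0.10 (quartiles -0.46 to 0.01) over 28 members to -0.05 (-0.26 to 0.07) over 20, and that of the 8 left out was -0.43, so shared reads remain open there. Handling before lysis that varied from culture to culture would spread the immediate early list within groups. The largest range of its median there was 0.12, and the gap between the isoform groups was 0.32 (0.16 to 0.25 with deltaNp63alpha, -0.28 to -0.15 with deltaNp63beta). The list was picked for differing between these groups on the same libraries, so setting the range beside the gap does not decide the question. Handling that differed between the groups as a whole could give that gap of 0.32 as well, and cannot be told apart from an effect of the isoforms, which stays open too.

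With 3 libraries against 3 there are 10 splits, so the share of splits as large cannot fall under 0.1. In fits of the 2 groups compared, the real split called 2228 genes for deltaNp63alpha against vector, 5879 for deltaNp63beta against vector and 4619 between the isoforms, the highest of the other splits called 0 in each, and 1 of 10 was as large.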

How the results depend on the processing

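Equal totals, quantile normalization, no mean-variance trend and library weights were chosen after seeing the data. So was the set without genes that lacked a position or shared a symbol between gene IDs. That set kept 358 of 359 results for named genes, and it does not test reads shared between near-identical genes. DESeq2 and limma-voom were not run, since the files hold no counts, and median-of-ratios factors were 1.00437 for each library and so test nothing. With a test against a 1.5-fold change, 134 genes were higher and 47 lower with deltaNp63alpha than with vector, 516 and 387 with deltaNp63beta, 231 and 187 between the isoforms, and 141 changed the same way with both; a stricter null leaves fewer calls by construction. The other settings kept each count within 1.5 times, except leaving out a library for the genes lower with deltaNp63alpha, which ranged from 640 to 1022. Their number was between 640 and 771 without any 1 vector or deltaNp63alpha library, and between 897 and 1022 without any 1 deltaNp63beta library. Only 641 and 640, without vector replicate 2 and 3, passed the limit, but 642 without deltaNp63alpha replicate 3 lay beside them. The lower numbers thus came with a library missing from either group compared, and the cause was not tested. The correlation of the changes ranged from 0.48 to 0.56 on leaving out a library. With a replicate block, 1053 genes were higher and 780 lower with deltaNp63alpha, 3121 and 2818 with deltaNp63beta, and 2435 and 2148 between the isoforms. Of 359 results for named genes, 138 lost their call under at least 1 setting, each of them with the 1.5-fold test, and none reversed. Calls were also lost 84 times on leaving out a library, 17 times with no mean-variance trend, 10 with quantile normalization, 6 each with no filter and with the replicate block, 5 with only the 2 groups compared, 2 with a pseudocount of 0.1, and 1 each with at least 1 CPM in 3 libraries, equal totals and library weights. Apart from leaving out a library and the 1.5-fold test, these were AURKA, CCNB1, DGKI, DIPK2B, ELF3, FDPS, FKBPL, H2AC6, ITGAV, PKM, TNC, TP73 and TPX2 with deltaNp63alpha against vector, ACTA2, COL1A1, KRT7, MT-CO1, MT-ND5 and PRLR with deltaNp63beta against vector, and DSEL, KDR, KRT7, MT-CO1, MT-ND1, MT-ND5 and TEK between the isoforms. Their adjusted p lay between 0.0506 and 0.585, except for MT-CO1, whose change quantile normalization sets to 0 by construction. Of 75 list results, 44 changed under at least 1 setting. An estimated correlation ended 20 calls. Some ended although the estimate lay below the preset 0.01, at 0.0047 for luminal and -0.073 for fibroblast markers with deltaNp63alpha against vector. A call lost there does not by itself show that members vary together. The fry test, which does not compare a list with other genes, gave 19 further calls and ended 1. It also called the fibroblast markers lower with deltaNp63beta against vector (adjusted p = 0.0438), where camera pointed up without a call (adjusted p = 0.547). Their median there was 0.47 and their mean -0.04, and the cause was not tested. Depth limits genes with low values, whose fold changes also depend on the pseudocount.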

Other observations

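The gene lists here were fixed before the data were examined, and of the tests in this part the scalings by equal totals and by quantiles were chosen after the result was seen. Interferon-stimulated genes were higher with deltaNp63beta than with deltaNp63alpha in 27 of 42 cases and lower in none (30 and 0 adjusted over the list alone; camera adjusted p = 1.8e-08, and adjusted p = 0.0284 with an estimated correlation). The antiviral genes OAS1 and RIGI differed by 1.17 ± 0.13 and 1.15 ± 0.13 and BST2 by 0.88 ± 0.06. Against vector, 23 rose and 2 fell with deltaNp63beta (25 and 2 adjusted over the list alone; camera adjusted p = 4.17e-05, but adjusted p = 0.0875 with an estimated correlation). With deltaNp63alpha 1 rose and 4 fell (1 and 4 adjusted over the list alone; camera adjusted p = 0.138, and 0.0286 without deltaNp63alpha replicate 1). NF-kB and inflammatory cytokine genes were higher between the isoforms in 17 and lower in 2 of 32 cases (18 and 3 adjusted over the list alone; camera adjusted p = 5.6e-07, and adjusted p = 0.0284 with an estimated correlation). The complement gene C3 differed by 1.35 ± 0.05 and the mitochondrial dismutase gene SOD2 by 1.20 ± 0.05. Against vector, 14 rose and 5 fell with deltaNp63beta (15 and 5 adjusted over the list alone; camera adjusted p = 0.000986, but adjusted p = 0.105 with an estimated correlation), and 6 rose and 9 fell with deltaNp63alpha (6 and 12 adjusted over the list alone; camera adjusted p = 0.15, and 0.0339 without deltaNp63alpha replicate 3). The cytokine genes IL1A and IL1B rose with both isoforms, by 1.56 ± 0.10 and 1.71 ± 0.13 with deltaNp63alpha and by 2.24 ± 0.10 and 2.72 ± 0.13 with deltaNp63beta.

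Sterol and fatty acid synthesis genes rose with deltaNp63beta against vector in 21 and fell in 1 of 34 cases (21 and 1 adjusted over the list alone; camera adjusted p = 5.94e-06, but adjusted p = 0.189 with an estimated correlation). FDPS rose by 1.01 ± 0.04, ACLY by 0.92 ± 0.05 and SCD by 0.88 ± 0.05. Between the isoforms 22 were higher and 1 lower (24 and 1 adjusted over the list alone; camera adjusted p = 7.31e-09, but adjusted p = 0.106 with an estimated correlation), and with deltaNp63alpha 6 rose and 3 fell, 5 and 4 with equal totals and 4 and 3 after quantile normalization (6 and 4 adjusted over the list alone; camera adjusted p = 0.978). Integrated stress response and unfolded protein response genes were higher between the isoforms in 18 and lower in 1, HERPUD1, of 34 cases (18 and 1 adjusted over the list alone; camera adjusted p = 3.62e-05, and adjusted p = 0.0269 with an estimated correlation). Against vector they went both ways, 17 higher and 11 lower with deltaNp63beta (18 and 12 adjusted over the list alone; camera adjusted p = 0.017, but adjusted p = 0.11 with an estimated correlation) and 14 and 14 with deltaNp63alpha (14 and 15 adjusted over the list alone; camera adjusted p = 0.867). The amino acid transporter genes SLC3A2 and SLC7A5 rose by 1.55 ± 0.05 and 1.34 ± 0.05 with deltaNp63beta. Glycolysis and hypoxia genes had 9 higher and 11 lower of 37 with deltaNp63beta (9 and 11 adjusted over the list alone; camera adjusted p = 0.932, median 0.04, mean -0.07), 6 and 4 with deltaNp63alpha (10 and 5 adjusted over the list alone; camera adjusted p = 0.295) and 10 and 10 between the isoforms (13 and 12 adjusted over the list alone; camera adjusted p = 0.497). With deltaNp63alpha the counts were 4 and 4 with equal totals and 3 and 5 after quantile normalization, and between the isoforms 8 and 12, and 9 and 10. Within it ANGPTL4 changed by -2.10 ± 0.06 with deltaNp63beta and CA12 rose by 1.48 ± 0.06.

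Poly(A) RNA was sequenced, so transcripts without a poly(A) tail may be missed, and 18 of 36 replication-dependent histone genes passed the filter. Some had low values, such as H2AC8, at 30.9, 17.6 and 20.7 with vector and 4.92, 4.14 and 4.93 with deltaNp63beta. Of the 18 tested, 9 fell with deltaNp63beta against vector and none rose (9 and 0 adjusted over the list alone, camera adjusted p = 0.00657, but adjusted p = 0.0589 with an estimated correlation). With deltaNp63alpha 2 fell (2 adjusted over the list alone; camera adjusted p = 0.0741, and 0.045 without vector replicate 3), and between the isoforms 3 were lower (3 adjusted over the list alone; camera adjusted p = 0.0577). Cytosolic ribosomal protein genes rose with deltaNp63beta in 38 of 73 cases, by a median of 0.17 (39 adjusted over the list alone; camera adjusted p = 1.51e-06, but adjusted p = 0.495 with an estimated correlation), and the median stayed above 0 with equal totals and quantile normalization, at 0.13 in both. Between the isoforms 35 were higher (37 adjusted over the list alone; camera adjusted p = 9.82e-09, but adjusted p = 0.438 with an estimated correlation), and with deltaNp63alpha 0 passed in limma, 1 at an unadjusted p under 0.05 (0 adjusted over the list alone; camera adjusted p = 0.764). Mitochondrially encoded mRNAs had 1 higher and 4 lower of 13 with deltaNp63beta, 1 and 3 after quantile normalization (1 and 4 adjusted over the list alone; camera adjusted p = 0.547) and the same counts between the isoforms, 1 and 5 with equal totals and 1 and 2 after quantile normalization (1 and 4 adjusted over the list alone; camera adjusted p = 0.116, and 0.026 and 0.0263 without replicate 1 of deltaNp63alpha or of deltaNp63beta). In both comparisons the gene higher in the main fit was MT-CO1, whose change quantile normalization sets to 0. The gene higher after quantile normalization was therefore another one. With deltaNp63alpha 0 passed in limma, 3 at an unadjusted p under 0.05 (0 adjusted over the list alone; camera adjusted p = 0.18, and 0.0445 without deltaNp63alpha replicate 1 and 0.00702 without vector replicate 2), and the median turned from 0.06 to -0.04 with quantile normalization.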
